A study of Mus musculus with 14 samples.

How the data were processed

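The samples were microglia, the resident macrophages of the brain, from C57BL/6 mice of 6 to 8 weeks kept under specific-pathogen-free (SPF) or germ-free (GF) conditions. Per the labels' protocols, microglia were enriched on a density gradient and sorted into lysis buffer as CD11b-positive cells with low CD45, and libraries were made from the 3' ends of polyadenylated RNA. The series design gives 1000 cells per brain and 7 samples per group, so each library was taken as 1 brain. The labels do not state that each came from a separate animal, and p-values measure the spread between these samples. The labels give neither sex, cage, litter, harvest time nor library batch. The groups came from the sample titles.

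Reads were aligned with TopHat to mm9, per the submitters' processing notes, which give no version. The counting tool, the treatment of molecular tags and of reads with several alignments, and the scaling method are not given in the sources used here. The deposited values are a signal per RefSeq transcript that is never negative, called normalized counts here. Their totals lay between 1356633 and 1520780 per library. Between 84.5% and 86.7% of the positive deposited values in a library were whole multiples of a single step, within 0.01 of a read, so each library appears to have been scaled by 1 factor. The remaining values were fractions of that step, so whole reads were not recovered and no count model was run. Dividing a library's total by its step gave its depth in read equivalents. Genes with near-identical copies, such as globins, ribosomal proteins and major histocompatibility genes, are uncertain where reads were shared between copies. Antisense and overlapping genes could not be told apart, because the use of strand is not given in the sources used here.

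The deposited table held 18487 rows. For each gene the row with the highest mean over the 14 libraries was kept, a choice made after the table was seen, which left 14219 genes. Of 2733 genes with several rows, 1913 had identical rows, and 217 rows had no symbol. Names were checked against the RefSeq gene table of GRCm38.p6, in which 18119 rows matched by accession. Transcript length and GC content came from GENCODE M21 and were found for 13894 genes. The reference is a later build than mm9, so no coordinates are given. The table held 0 genes matched to the Y chromosome and 0 members of the list of mitochondrially encoded transcripts, so neither kind was analysed here.

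Differences are GF minus SPF on the log2 scale of the value plus a pseudocount of 1.44 normalized counts, a fixed fraction of the mean library total, which understates the change of genes with low values. Genes with a mean of at least 7.22 normalized counts, 5 times the pseudocount, were tested, which kept 8823. The test was limma 3.58.1 in R 4.3.3 with a mean trend in the spread, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Every adjusted p of a gene comes from this model unless another test is named. A gene is said to have risen or fallen where it passed.

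Before the data were examined, 38 gene lists were written from textbook knowledge, as were the tests, the alternatives and the rule for naming genes. The 29 lists with at least 3 members tested were compared with the other genes by limma's camera with a preset correlation of 0.01 between genes, adjusted by Benjamini-Hochberg over the lists. Camera with an estimated correlation and fry, a rotation test of whether a list's genes move on balance one way, were run beside it. Members past the threshold were also counted when adjusted over the list alone. Summed values of the marker lists of other cell types were compared by an exact permutation test on the log2 scale over the 3432 ways to divide 14 libraries into 7 and 7, and so was the share of the squared distance between libraries that lay between the groups. The mean of each list per library was compared in the same way, adjusted over the 29 lists, a test added after the data were seen. The smallest two-sided p this allows is 0.000583.

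The rule named the 10 largest rises and the 10 largest falls among the genes past the threshold. It also took up to 4 members of each list with the smallest adjusted p, or the member with the smallest p where none passed. Finally it took 17 genes whatever their result, among them Csf1r, Sfpi1, Cx3cr1, Tmem119, P2ry12, Irf8, B2m, Cd86, Il1a, Fcgr2b, Mapk8, Jak3, Ddit4, Ccnd3, Bcl2 and Hdac1. Genes named outside this rule are said to be so.

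The procedure was tested on simulated data for this comparison, with 200 of 8803 tested genes changed. It recovered 20.9% of genes changed 1.5-fold, 61.2% of those changed 2-fold and 87.9% of those changed 4-fold, and 5.04% of its calls were unchanged genes. With no change simulated it called 1 gene. With the lysosome list raised 1.3-fold it called 2 lists, of which 1 was the lysosome list. Genes were drawn independently there, so the simulation does not test whether the preset correlation suits the list calls. In the data the estimated correlation of the 7 lists called ran from -0.003 for developing microglia to 0.37 for ribosomal proteins. Alternatives covered the pseudocount, the filter, the scaling, the model of the spread, a rank test, the replicate number as a block and the omission of each library. Added after the data were seen were the use of every deposited row, thinning to a common depth, removal of length and GC trends, and the omission of 3 libraries together. Figures were drawn with matplotlib 3.10.9.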

Results

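Gene expression was measured in microglia sorted from the brains of SPF and GF mice, in 7 libraries per group, to ask how the microglial transcriptome differs when mice are raised without microorganisms. Depth per library ranged from 907575 to 1634710 read equivalents in SPF, with a mean of 1314540 ± 224580 (SD, n = 7), and from 680091 to 1190274 in GF, with a mean of 1083560 ± 181132 (SD, n = 7, exact permutation p = 0.0542). More genes were at 0 in GF libraries, 25.1% ± 1.54 against 21.9% ± 1.59 (SD, n = 7 each, exact permutation p = 0.00175).

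Germ-free microglia differed from SPF microglia in 596 of 8823 genes tested. In GF, 325 genes rose and 271 fell (limma, Benjamini-Hochberg adjusted p under 0.05), a balance that turned to 264 and 328 with upper-quartile scaling and to 257 and 283 with quantile normalization. Among the largest rises were Ddit4, an inhibitor of mTORC1 signalling, and Tsc22d3, a glucocorticoid-induced regulator of transcription. Ly86, which encodes MD-1, the partner of the Toll-like receptor homologue CD180, fell with the smallest adjusted p of all genes tested, and the purinergic receptor gene P2ry12 also fell. The genes that rose changed less and were more abundant, with a median log2 difference of 0.63 and a median mean of 201 normalized counts, against -0.98 and 61.6 for those that fell. The count of falls was 171 without SPF 7. With length and GC trends removed, 297 rose and 161 fell, and 340 of the 596 calls were shared. Without GF 1, with high class II transcripts, GF 6, with the lowest depth, and SPF 2, lowest in depth among SPF, 154 genes rose and 166 fell. Among all 8823 genes tested, all GF libraries lay above all SPF libraries in 113 and below them in 79, where chance gives 0.0291% of genes, or 2.57, in each direction. At an unadjusted p under 0.05, 952 genes were higher and 983 lower.

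The whole profiles also differed by housing. Of the squared distance between libraries, 15.3% lay between the groups (exact permutation p = 0.000583, the smallest these 3432 divisions can give). The first principal component held 16.6% of the variance and placed SPF libraries between -38.04 and -9.52 and GF libraries between 11.51 and 37.87. GF 6 stood alone on the second component, at 63.5.

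**Figure D1:**
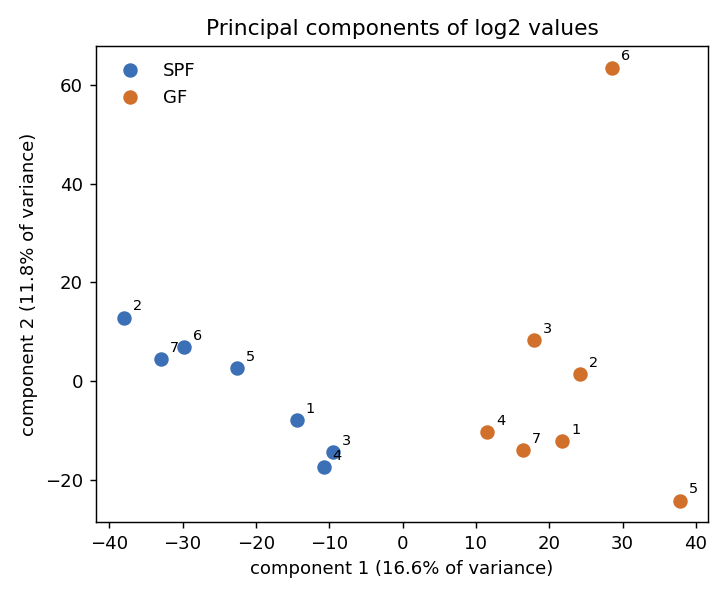
Principal components of the log2 values of the genes tested, component 1 (16.6% of variance) on the x axis and component 2 (11.8%) on the y axis, with 1 point per library, coloured by group and numbered by replicate. The 7 GF libraries lie at 11.51 or above on component 1 and the 7 SPF libraries at -9.52 or below, and GF 6 lies at 63.5 on component 2.

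Genes that mark microglia moved in both directions. P2ry12 fell from 2633 ± 307 to 1371 ± 193 normalized counts (SD, n = 7 each), a log2 difference of -0.95 ± 0.09 (SE, adjusted p = 6.97e-07), and was lower in all 7 GF libraries than in any SPF library. P2ry13, a related receptor gene, fell by 0.70 on the log2 scale, and Sparc, which encodes a secreted matrix-binding protein, fell by 0.33. P2ry6, a receptor for uridine diphosphate, rose by 0.46 and Selplg, which encodes a selectin ligand, by 0.30. Tmem119 rose by 0.27 and Csf1r, the receptor on whose signals microglia depend, by 0.30 ± 0.06 (SE), from 14980 ± 840 to 18463 ± 1365 (SD, n = 7 each). Quantile normalization, which gave Csf1r -0.05 (adjusted p = 0.612), sets values by rank and nearly fixed that of Csf1r, which ranked 3 to 5 of all genes tested in every library. Of 29 other settings, 4 ended the call of Tmem119, 3 that of Csf1r, quantile normalization included, 2 that of Selplg, and 1 those of Sparc and of P2ry13. Cx3cr1, the fractalkine receptor gene, stood at 6211 ± 806 in SPF and 7034 ± 1295 in GF (SD, n = 7 each, adjusted p = 0.350). Of the 30 microglia identity genes tested, 5 rose and 5 fell, or 5 and 10 when adjusted over the list alone, and the list as a whole was not called (camera adjusted p = 0.208).

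Markers of developing microglia included 4 genes that rose of 10 tested, and none fell. The same counts held when adjusted over the list alone. Crybb1, a crystallin gene expressed in young microglia, rose from 1139 ± 145 to 1864 ± 260 (SD, n = 7 each), and Apoe, which encodes apolipoprotein E, from 1377 ± 239 to 2479 ± 551, a log2 difference of 0.83 ± 0.13 (SE, adjusted p = 0.000246). Ctsb, which encodes a lysosomal protease, rose by 0.39. Lgals3, which encodes galectin-3, rose by 2.03 from 3.85 normalized counts, but its call was lost in 17 of 28 settings, among them the omission of any of 10 libraries, namely SPF 1, 2, 3, 4 and 7 and GF 1, 3, 4, 6 and 7 (adjusted p 0.0503 to 0.0976). The list was called higher in GF (camera adjusted p = 0.0131), with a mean log2 difference of 0.17. That call was lost with an estimated correlation (adjusted p = 0.0922 with an estimated correlation), and the mean turned to -0.09 with no filter on low values. The mean of its members per library did not pass (exact permutation adjusted p = 0.488). Among adult microglia markers 3 of 17 rose and 3 fell, or 7 and 7 when adjusted over the list alone (camera adjusted p = 0.796). Those that fell were P2ry12, B2m and Il1a.

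Lysosomal genes were higher in GF, and the list of disease-associated microglia genes was called higher by camera at its preset correlation. Of 24 disease-associated genes tested, 7 rose and 0 fell, or 8 and 0 when adjusted over the list alone (camera adjusted p = 0.000218, adjusted p = 0.112 with an estimated correlation). The mean of its members per library did not pass (exact permutation adjusted p = 0.146). Of the 24 genes, 18 stood above 0 and 6 below. Spp1, Lpl, Clec7a, Cst7 and Itgax, all of low abundance, did not pass, with log2 differences of -1.58, -0.16, -0.13, -0.10 and 0.11. Trem2 and Fth1 rose by 0.28 and 0.33 but did not pass under quantile normalization (adjusted p = 0.180 and 0.133). These members were chosen after their values were seen. All tested members of the developing microglia list except Crybb1 and Mcm5 are also on the disease-associated list, among them Apoe, Ctsb and Lgals3. The calls of these lists are therefore not independent. Ctsb, Ctsd and Ctsz, 3 of the 7 disease-associated genes that rose, are also on the lysosomal list, which shares 6 tested members. Ctsz, which encodes a lysosomal carboxypeptidase, rose from 1372 ± 228 to 2027 ± 74 (SD, n = 7 each), and Ctsd, which encodes an aspartic protease, by 0.34. Ctsd ranked 3 or 4 in every library, which nearly fixed its value under quantile normalization, at 0.03 (adjusted p = 0.701). Of 39 lysosomal genes, 12 rose and 1 fell, or 17 and 2 when adjusted over the list alone (camera adjusted p = 2.87e-06, adjusted p = 0.112 with an estimated correlation). Lamp1, which encodes an abundant membrane protein of lysosomes, rose by 0.45 ± 0.08 (SE), and Ctsa, the gene of protective protein, by 0.39.

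Glucocorticoid response genes were higher in GF, and their mean was higher in all 7 GF libraries than in any SPF library (exact permutation adjusted p = 0.00845 over the 29 lists). Of 15 tested, 7 rose and 0 fell, the same counts as when adjusted over the list alone, with a mean log2 difference of 0.70. The list was called higher (camera adjusted p = 5.03e-07, adjusted p = 0.0922 with an estimated correlation). Ddit4 rose from 40.97 ± 24.1 to 460 ± 342 (SD, n = 7 each), a log2 difference of 3.28 ± 0.41 (SE, adjusted p = 1.59e-05). Its lowest GF library stood at 116 and its highest SPF library at 72.9. Tsc22d3 rose from 22.8 ± 7.7 to 122 ± 85 (SD, n = 7 each), a log2 difference of 2.09 ± 0.34 (SE, adjusted p = 0.000343). Sult1a1, a sulfotransferase gene, rose by 1.21 and Nfkbia, which encodes the NF-kB inhibitor IkB-alpha, by 0.82. Immediate early genes, which respond to stimuli within minutes, gave 1 rise and 0 falls of 15 tested, or 2 and 1 when adjusted over the list alone (camera adjusted p = 0.908). The gene that rose was Rhob, by 0.66.

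**Figure D2:**
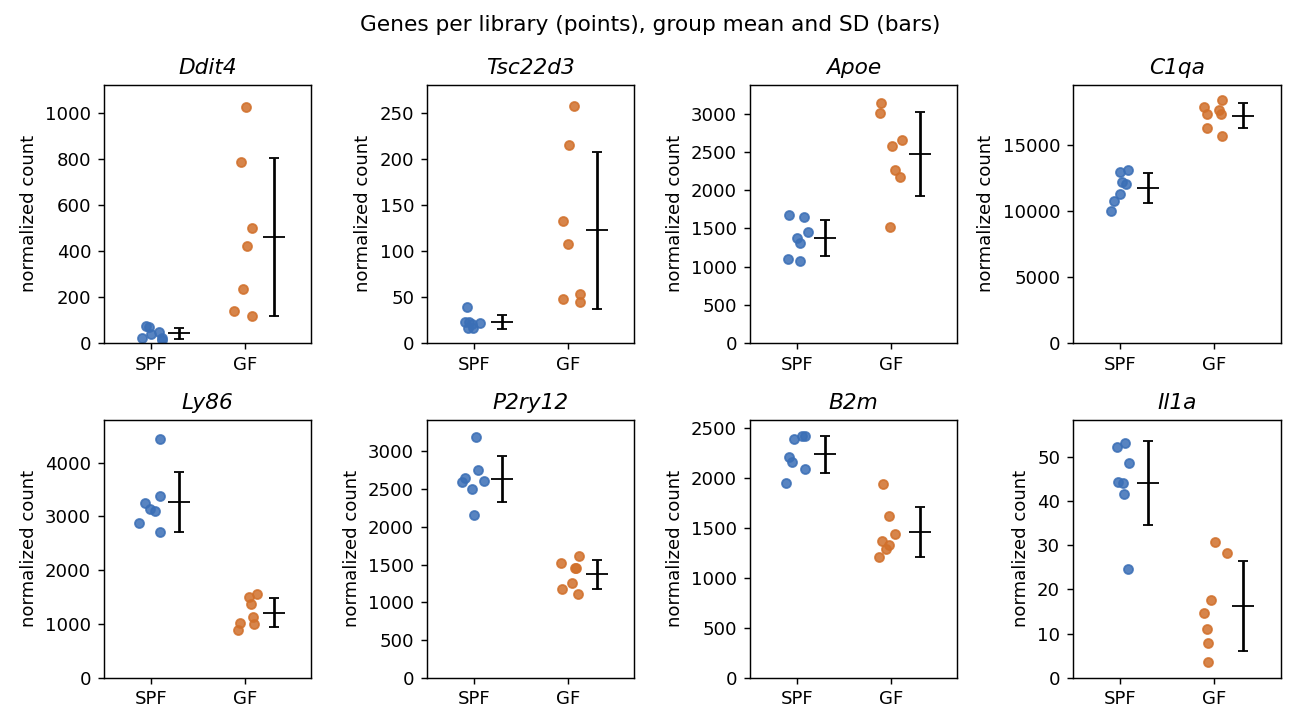
Normalized counts of 8 genes, with group on the x axis, 1 point per library, and the mean and SD of each group (n = 7) beside the points. Ddit4, Tsc22d3 and C1qa were higher in all GF libraries than in any SPF library, and Ly86, P2ry12 and B2m lower, while Apoe and Il1a overlapped between groups.

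Interferon-related genes were lower in GF. Of 30 type I interferon response genes tested, 0 rose and 5 fell, or 0 and 7 when adjusted over the list alone, with a mean log2 difference of -0.43 (camera adjusted p = 0.00134, adjusted p = 0.0922 with an estimated correlation). Rtp4, an interferon-induced gene, fell from 36.8 ± 10.5 to 14.4 ± 10.1 (SD, n = 7 each), and Irf9, part of the transcription factor complex that type I interferon activates, from 85.8 ± 20.3 to 49.1 ± 7.0. Trim30a, an interferon-induced gene, fell by 0.92. The call of Trim30a was lost in 9 of 29 settings, among them without any of SPF 2, 6 and 7 and GF 3 and 5 (adjusted p 0.0638 to 0.0720). B2m, the light chain of major histocompatibility class I, fell from 2239 ± 183 to 1459 ± 251 (SD, n = 7 each), a log2 difference of -0.63 ± 0.09 (SE, adjusted p = 0.000139). Cd86, a costimulatory ligand gene, fell by 1.16, and H2-DMb1, which acts in loading of class II molecules, rose by 0.65. Of the 25 antigen presentation and costimulation genes 1 rose and 2 fell, or 2 and 2 when adjusted over the list alone (camera adjusted p = 0.542). GF 1 alone held high class II transcripts, with 931 normalized counts of H2-Aa and 1195 of Cd74 against at most 11.8 and 140 in the other 13 libraries.

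Receptors and signalling genes of innate immunity changed in part. Ly86 fell from 3275 ± 560 to 1208 ± 268 (SD, n = 7 each), a log2 difference of -1.45 ± 0.12 (SE, adjusted p = 3.84e-08), with all GF libraries below all SPF libraries. Nlrp3, an inflammasome sensor gene, fell by 0.78, while Cd14, a lipopolysaccharide coreceptor gene, rose by 0.48. Nlrp1b, another inflammasome sensor gene, fell by 1.20, a call lost in 17 of 28 settings, among them without any of SPF 1, 2, 3, 5, 6 and 7 and GF 1, 2, 3 and 5 (adjusted p 0.0507 to 0.0947). The call of Cd14 was lost in 11 of 29 settings, among them without any of SPF 2 and 6 and GF 2, 3 and 7 (adjusted p up to 0.0642). Of 33 pattern recognition genes 1 rose and 3 fell, both over all genes and when adjusted over the list alone (camera adjusted p = 0.118), and fry called the list lower (adjusted p = 0.0140), as did the mean of its members per library (exact permutation adjusted p = 0.0253). Among signalling genes, Jak3 fell by 1.02 and Mapk8, the gene of the stress kinase JNK1, fell by 1.86, while Rela, an NF-kB subunit gene, rose by 0.75. The call of Mapk8 was lost in 15 of 28 settings, among them without any of SPF 1, 2, 5, 6 and 7 and GF 2, 3 and 7 (adjusted p 0.0538 to 0.0815). In that list 3 of 39 rose and 3 fell, or 4 and 5 when adjusted over the list alone (camera adjusted p = 0.660), and the mean of its members per library was lower (exact permutation adjusted p = 0.0203).

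Cytokine genes moved both ways. Il1a, which encodes interleukin-1 alpha, fell from 44.1 ± 9.6 to 16.2 ± 10.1 (SD, n = 7 each), a log2 difference of -1.57 ± 0.35 (SE, adjusted p = 0.00666), and the chemokine gene Ccl12 fell by 0.98. Tgfb1, which encodes transforming growth factor beta 1, rose from 693 ± 130 to 1166 ± 87 (SD, n = 7 each), and Ifngr1, an interferon gamma receptor gene, by 0.35. In the list of cytokines, chemokines and receptors, 3 of 28 rose and 2 fell, or 4 and 6 when adjusted over the list alone (camera adjusted p = 0.954). Among Fc receptor, complement and phagocytosis genes, C1qa, a subunit of the first complement component, rose from 11758 ± 1143 to 17223 ± 938 (SD, n = 7 each), and C1qc rose by 0.49. Under quantile normalization, which leaves little room to genes ranked 4 to 7 and 7 to 10 in every library as these were, the differences were 0.15 for C1qa (adjusted p = 0.0548) and 0.27 for C1qc (adjusted p = 0.0552), and C1qb, chosen after its values were seen, turned from 0.35 to -0.04. Fcgr2b, the inhibitory Fc gamma receptor gene, fell by 0.83 and Elmo1, an engulfment adaptor gene, fell by 1.69. Of the 29 genes 5 rose and 3 fell, or 10 and 5 when adjusted over the list alone (camera adjusted p = 0.223).

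Ribosomal protein genes were called higher as a list. Of 75 tested, 37 rose and 0 fell, or 43 and 0 when adjusted over the list alone, with a mean log2 difference of 0.38 (camera adjusted p = 6.4e-24, adjusted p = 0.112 with an estimated correlation). Rpl26 rose from 343 ± 51 to 567 ± 63 (SD, n = 7 each) and Rps26 from 177 ± 17 to 289 ± 28. Rps29 rose by 0.64 and Rpl35 by 0.69. Of 73 nuclear-encoded genes of oxidative phosphorylation, 8 rose and 0 fell, or 11 and 0 when adjusted over the list alone (camera adjusted p = 1.86e-05, adjusted p = 0.251 with an estimated correlation). Ndufa3, a complex I subunit gene, rose by 0.73, Uqcrc1 and Uqcrq, of complex III, by 0.71 and 0.59, and Atp5d, of the ATP synthase, by 0.58. The call of this list ended when trends with length and GC content were removed (mean 0.12 against 0.19, camera adjusted p = 0.0602). Of the 22 glycolysis and hypoxia genes 0 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.660). Eno1, a glycolytic enzyme gene, had the smallest p, with a log2 difference of 0.33 ± 0.11 (SE, adjusted p = 0.0740).

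**Figure D3:**
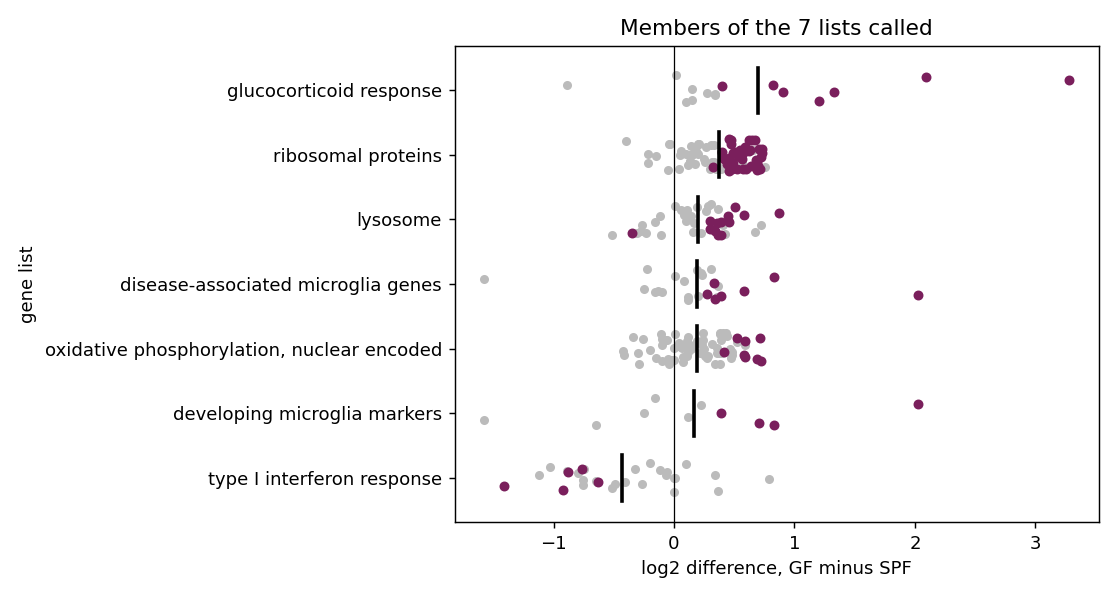
Log2 difference, GF minus SPF, on the x axis for each tested member of the 7 lists called, with lists on the y axis. Dark points passed the threshold, grey points did not, and black bars are list means, which run from -0.43 for the type I interferon response to 0.70 for the glucocorticoid response.

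Among transcription factors, Cebpa rose by 0.64, Cebpb by 0.51 and Sfpi1, now Spi1, which encodes PU.1, by 0.44, while Fli1 fell from 184 ± 37 to 86.4 ± 21.7 (SD, n = 7 each). The call of Sfpi1 was lost in 8 of 29 settings, among them without SPF 5 or SPF 7 (adjusted p 0.0573 to 0.0632). Irf8 stood at 735 ± 120 in SPF and 634 ± 83 in GF (SD, n = 7 each, adjusted p = 0.292). Of 24 such genes 3 rose and 1 fell, or 4 and 1 when adjusted over the list alone (camera adjusted p = 0.954). In survival and G1 genes, Bcl2, which opposes apoptosis, rose from 13.2 ± 9.5 to 39.0 ± 12.5 (SD, n = 7 each), Ccnd3, which encodes cyclin D3, rose by 0.74, and Casp8, an initiator caspase gene, fell by 1.03. The call of Ccnd3 was lost in 13 of 29 settings, among them without any of SPF 1, 2, 6 and 7 and GF 1, 3, 5 and 6 (adjusted p 0.0504 to 0.0800). With Ddit4, 3 of 34 rose and 1 fell, or 8 and 1 when adjusted over the list alone (camera adjusted p = 0.352). No gene of the 7 tested of S and G2/M phases passed, and 0 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.437). The smallest p there was that of Mcm6, a replicative helicase gene, with 12.6 ± 6.8 in SPF and 4.0 ± 3.9 in GF (SD, n = 7 each, adjusted p = 0.0741).

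Of the remaining lists none was called. Kdm6b, a histone H3 lysine 27 demethylase gene, rose by 0.73 as the single call among 34 chromatin modifiers, also when adjusted over the list alone (camera adjusted p = 0.908). Hdac1, a histone deacetylase gene, had a log2 difference of -0.47 ± 0.19 (SE, adjusted p = 0.141). In the list of heat shock and unfolded protein response, Dnajb1 rose by 0.79 and Hspa8 by 0.49, both cytosolic chaperone genes, and Hspa5, the chaperone of the endoplasmic reticulum, fell by 0.83. There 2 of 21 rose and 1 fell, or 3 and 1 when adjusted over the list alone (camera adjusted p = 0.542). Of 22 cholesterol and lipid genes 2 rose, or 2 with 1 fall when adjusted over the list alone, namely Apoe and Abcg1, a sterol exporter gene, by 0.55 (camera adjusted p = 0.370). The call of Abcg1 was lost in 13 of 29 settings, among them without any of SPF 1, 2, 4 and 7 and GF 4 and 5 (adjusted p 0.0529 to 0.0758). Of 35 proteasome and ubiquitin genes 1 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.437). Of 4 genes of short-chain fatty acid and aryl hydrocarbon receptor signalling, 0 passed in either count (camera adjusted p = 0.954), and the lactate and monocarboxylate transporter gene Slc16a1 had the smallest p, with -0.78 ± 0.36 (SE, adjusted p = 0.203). The mean, median and test differed in sign for the lists of proteasome, heat shock, transcription factor, short-chain fatty acid and border-associated macrophage genes.

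The largest changes beyond these lists were mostly in genes of low abundance. Xist, the RNA that silences an X chromosome in female cells, fell from 139 ± 47 to 27.7 ± 14.1 (SD, n = 7 each), a log2 difference of -2.36 ± 0.29 (SE, adjusted p = 1.17e-05). Its GF libraries ranged from 8.68 to 49.4 and its SPF libraries from 93.2 to 202. Ero1lb, now Ero1b, an oxidoreductase of the endoplasmic reticulum, fell from 26.5 ± 9.3 to 2.9 ± 2.5 (SD, n = 7 each). Falls of a log2 difference between -2.80 and -2.28 were also found in Nlrp1c (a pseudogene), Tmco6, Fam129a (now Niban1), Agtpbp1, Polr3f, Far1, Slc8a1 and C78339 (now Fam8a1), which had means of 14.5 to 36.9 in SPF. Iqgap1, which encodes a cytoskeletal scaffold, rose by 2.36, Notch4, a Notch receptor gene, by 1.59 and Ttyh2 by 1.40. The calls of Foxp4, with a log2 difference of 2.13, Agpat4, with 2.04, and Nr1d1, a clock repressor gene, with 1.42, were lost in 20, 4 and 8 of 28 settings, among them the omission of any of 11, 4 and 5 libraries respectively (adjusted p 0.0580 to 0.0984, 0.0504 to 0.0614 and 0.0566 to 0.0668). Those of Foxp4 were SPF 1, 2, 5, 6 and 7 and GF 1, 2, 3, 5, 6 and 7, those of Agpat4 SPF 7 and GF 2, 3 and 5, and those of Nr1d1 SPF 6 and 7 and GF 2, 3 and 5. Of the named calls for which no count of settings is given, those of Jak3, Cd86, Cebpb, Ifngr1 and Notch4 were lost in 3 of 29 settings. Those of Atp5d, C1qc, Ctsd, H2-DMb1 and Hspa8 were lost in 2 of 29, those of Rtp4 and Slc8a1 in 2 of 28, and the others in at most 1.

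Markers of other cell types were present at low to moderate levels in both groups. Summed over their lists and adjusted over 13 comparisons, pericyte and smooth muscle markers were lower in GF, 6.82 ± 4.17 against 15.2 ± 6.1 normalized counts (SD, n = 7 each, exact permutation adjusted p = 0.0379). Most of that sum was Acta2, at 5.62 and 13.4. The sum of neutrophil markers was higher, 632 ± 47 against 560 ± 37 (SD, n = 7 each, exact permutation adjusted p = 0.0341), but its main members moved apart. Elane, the neutrophil elastase gene, rose by 0.65, while Csf3r, a cytokine receptor gene chosen after its values were seen, stood at 344 in SPF and 292 in GF (adjusted p = 0.225). Summed oligodendrocyte markers were 1902 ± 256 in SPF and 1916 ± 127 in GF (SD, n = 7 each, exact permutation adjusted p = 0.885). Most of that sum was Trf, at 1599 in SPF and 1648 in GF, while Mbp stood at 27.8 and 42.1. Sums of neuron, astrocyte, endothelial, border-associated macrophage, monocyte, T and NK cell, B cell, erythroid and choroid plexus markers did not pass (exact permutation adjusted p 0.131 to 0.895). Stab1, at 470 in SPF and 562 in GF, made most of the border-associated macrophage sum. Slc1a3, at 217 and 192, made most of the astrocyte sum. Trf, Stab1 and Slc1a3 were chosen after their values were seen, and the sums they dominate say little of the other markers. None of the neuron, astrocyte, oligodendrocyte, endothelial or border-associated macrophage lists was called by camera (adjusted p 0.437 to 0.954). Adjusted over the list alone, 1 marker was higher and 1 lower in each of the border-associated macrophage and neutrophil lists. In the B cell list 1 was higher, and 1 was lower in each of the pericyte and T and NK cell lists. The neuron, astrocyte, oligodendrocyte, endothelial, monocyte and erythroid lists had 0. The B cell and neutrophil lists had only 2 markers tested. The pericyte and T and NK cell lists had 1 each, Acta2 and Il7r, so their p-values were unadjusted there. Over all genes these 2 did not pass (adjusted p = 0.158 and 0.133). No choroid plexus marker passed the filter on low values. Single markers with the smallest p in their lists did not pass either, with log2 differences of -1.91 for Mrc1, -1.31 for Il7r, 0.97 for Cd22, -1.01 for Acta2, 0.61 for Mbp, -0.55 for Pecam1, -1.02 for Camk2a, 0.22 for Lyz2 and 0.91 for Hbb-b1. GF 6 held 1839 normalized counts of erythroid markers, against 28.2 to 62.5 in the other libraries.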

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

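The 3 tests of the glucocorticoid response genes were chosen after the result was seen, as were thinning to a common depth and the value without Per1. In each group of 7, the highest or lowest library was compared with the others by Dixon's gap, and 20 of 242 groups had a library far from the rest, where chance gives about 1 in 20. GF 6 stood apart in depth, with 680091 read equivalents, in its median correlation with its own group, 0.846, and on component 2, at 63.5. It also held 1839 normalized counts of summed erythroid markers, 420 of Hbb-b1 and 17.4 of Pecam1, an endothelial gene. SPF 7 was low in Il1a, at 24.7 normalized counts, in Uqcrc1, at 106, and in summed astrocyte markers, at 217. SPF 2 was low in P2ry13, at 1524, and high in Cebpb, at 328. Kdm6b was low in SPF 4, at 70.2, and in GF 5, at 142. Tsc22d3 was high in SPF 5, at 39.2, which stayed below the lowest GF library at 44.3. Rela was low in GF 3, at 165, Ctsa was low in GF 4, at 1904, and summed B cell markers were low in SPF 6, at 79.6. Of the clock genes, Per3 was at 0 in GF 1 and Cry1 at 0 in SPF 6 and in GF 4.

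Glucocorticoid response genes were higher in GF, with a mean log2 difference of 0.70 over 15 genes. The tests do not decide on hypoxia during isolation, since the 22 glycolysis and hypoxia genes had a mean of -0.0797 (95% interval -0.21 to 0.05, exact permutation p = 0.207) but went both ways, 9 above 0 and 13 below. Stress of handling or dissociation also stays open and cannot be told apart from housing, since 15 immediate early genes had a mean of -0.0946 (95% interval -0.33 to 0.14, exact permutation p = 0.399), with 4 above 0 and 11 below, while Rhob, Dnajb1 and Hspa8 rose. A different time of harvest may contribute and cannot be told apart from housing, since the labels give no time and clock output minus opposite-phase genes differed by 1.13 (95% interval -0.00296 to 2.27, exact permutation p = 0.0554), or 0.93 without Per1, which is on both lists (95% interval -0.24 to 2.10, exact permutation p = 0.108). A response of microglia to housing, by way of circulating glucocorticoids or otherwise, stays open and was not tested.

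Xist and Malat1, both nuclear RNAs, were lower in GF, Malat1 by a log2 difference of -1.79 ± 0.25 (SE) and chosen after its values were seen. After thinning to a common depth Malat1 stood at -1.78 (95% interval -2.27 to -1.29). Thinning keeps the expected value of an abundant gene, so this test could hardly have come out otherwise. It does not decide on lower depth of the GF libraries. The call of Xist was kept in all 29 settings, thinning included. A lower yield of nuclear RNA in GF is a candidate explanation. The 28 other nuclear-retained transcripts had a median of -0.33 (95% interval -0.48 to -0.16) and were called lower than other genes by camera. The median was -0.34 before a gene entered by a wrong synonym was removed. This list, like that of the escape genes below, was not among those written before the data were examined. Its call was not tested with an estimated correlation, by its mean per library or with length and GC trends removed. Most of its members did not pass, and Rbm39 and Mat2a, chosen after their values were seen, stood above 0. Male cells in GF libraries cannot be told apart from a fall of Xist in female cells, because 6 genes that escape X inactivation had a median of -0.00573 (95% interval -1.07 to 0.26) and the labels give no sex. The table held no Y-linked gene to check it. Of the escape genes, Ddx3x fell by 0.49 (adjusted p = 0.0487). The largest difference was that of 5530601H04Rik, -1.65 ± 0.54 (SE, adjusted p = 0.0627), and Kdm5c stood at -0.05. Mid1, Eif2s3x and Kdm6a stood above 0, but Mid1 had a log2 difference of 0.39 ± 0.82 (SE) and a lower mean in GF, 34.1 against 48.4. All were chosen after their values were seen. A lower level of Xist and Malat1 in living GF microglia also stays open and was not tested.

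More genes were at 0 in GF, and 133 genes fell by a log2 difference of 1 or more in size, against 27 that rose as far. Lower depth is argued against as the whole cause, since after thinning 27.4% ± 1.03 of genes were at 0 in GF and 24.9% ± 1.15 in SPF (SD, n = 7 each), a difference of 2.44 points (95% interval 1.17 to 3.71, exact permutation p = 0.00291). Fewer molecules captured before amplification could give the same picture and cannot be told apart from lower expression, because the 8310 genes not called after thinning to a common depth varied between GF libraries 1.05 times as much as between SPF libraries, and 1.02 times without GF 6. Silencing of genes in GF microglia stays open and was not tested.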

How the results depend on the processing

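Thinning, removal of length and GC trends, every deposited row and the joint omission of GF 1, GF 6 and SPF 2 were chosen after the data were seen. The counts of genes higher and lower, 325 and 271, stayed within 1.5 times of these under the pseudocounts, filters, scalings, quality weights and robust spread, although 2 scalings turned their balance. They were 160 and 161 with no mean trend, 155 and 118 by the exact rank-sum test, and 154 and 166 without GF 1, GF 6 and SPF 2, where fewer libraries were left. Leaving out 1 library gave 242 to 337 higher and 171 to 291 lower, with 171 without SPF 7. Removal of length and GC trends gave 297 and 161, thinning 287 and 226, and every deposited row 415 and 373 of 11618 rows. With the replicate number as a replicate block the counts were 286 and 241, of which 496 were shared, but libraries with the same number did not pair, with a median correlation of -0.0019 against -0.00423 for other numbers. The separation of the groups was 13.2% to 18.8% in all settings. The 7 lists called were 6 to 9 in other settings, 8 by fry and 0 with an estimated correlation. Correlated members do not account for every such loss. The estimated correlation of the developing microglia list was -0.003, below the preset 0.01, and that of the type I interferon list was 0.024. The developing microglia list turned to -0.0877 with no filter (adjusted p = 0.372), and oxidative phosphorylation was 0.12 with length and GC trends removed (adjusted p = 0.0602). Csf1r was -0.0471 under quantile normalization (adjusted p = 0.612), which nearly fixes it by its rank of 3 to 5 in every library and says little of its stability. Most of the other highly abundant genes were also higher in GF, while Sparc and Tmsb4x were lower. Among those higher was Actb, from 22102 to 25679 normalized counts. Actb and Tmsb4x were chosen after their values were seen. Whether Csf1r rose beyond a shift shared by abundant genes was not tested. Irf8 passed under quantile normalization at -0.34, Mrc1 without GF 2 at -2.36, and Eno1 without GF 4 at 0.37. Of 80 named genes called, 34 passed in every setting in which they were tested. Among these, Ero1lb, Far1, Iqgap1 and Tmco6 were tested in 28 of the 29 settings. Over their settings 2098 results were the same, 201 were weaker, 34 of them by the exact rank-sum test and 24 with no mean trend, and 1 was reversed. Where no cause is given, the cause was not tested. The planned count models were not run, because whole reads could not be recovered for nearly all values, nor were lists on every deposited row, where rows of 1 gene repeat. The simulation recovered 20.9% of 1.5-fold changes, so at this depth and spread most changes of that size would be missed.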

Other observations

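Genes outside the naming rule are given here, all chosen after their values were seen. Among the nuclear-retained transcripts, Clk4 fell by 1.095 on the log2 scale, Clk1 fell by 0.73, Ddx17 fell by 0.64, Srsf5 fell by 0.46 and Ddx5 fell by 0.34. Clk1 and Clk4 encode kinases of splicing factors, Srsf5 a splicing factor, and Ddx5 and Ddx17 RNA helicases. Son, which encodes a nuclear speckle protein, fell from 208 ± 22 to 102 ± 28 normalized counts (SD, n = 7 each), while Neat1, a nuclear noncoding RNA, had a log2 difference of -0.32 ± 0.19 (SE, adjusted p = 0.344). Malat1 fell from 1217 ± 422 to 372 ± 189 (SD, n = 7 each). Gpr34, a microglial receptor gene, fell by 1.03. Cst3, which encodes cystatin C and was the most abundant transcript, rose from 55556 to 68920 normalized counts, although quantile normalization sets its difference to 0 because it has the same rank in every library.

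Of the clock genes, Per1 rose by 1.33 and Nr1d1 by 1.42, while the log2 differences of Tef, Dbp, Per3, Arntl and Cry1, 0.17, 0.59, -0.90, -0.97 and -0.26, did not pass. Fkbp5, a glucocorticoid-induced cochaperone gene, rose from 99.4 to 200.1 normalized counts. Within the 7 GF libraries Ddit4 varied with the mean of the 6 other glucocorticoid response genes that rose, with Pearson's r = 0.974 (exact permutation p = 0.000595, adjusted 0.00119) and Spearman's rho = 1 (exact permutation p = 0.000397, the smallest 7 libraries can give, adjusted 0.000794). Without the 2 libraries farthest from the median r was 0.940. Within the 7 SPF libraries r was 0.269 (exact permutation p = 0.557), rho was 0.321 (exact permutation p = 0.498) and r without 2 libraries was 0.00446. These 2 relations were the ones computed, and the difference between them was not tested. GF 5, 6 and 7 were the highest GF libraries in Ddit4, at 1027, 785 and 501, against at most 420. SPF 5, 6 and 7 were the highest SPF libraries, at 72.9, 70.1 and 48.0, against at most 39.8. Tsc22d3 was also highest in GF 5, 6 and 7, at 257, 214 and 132, but SPF 6 was the lowest SPF library, at 16.0. The labels give no batch or harvest time, so a cause tied to library number was not tested. SPF 1 held 719 normalized counts of G530011O06Rik, against at most 66.2 elsewhere.

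Chance divisions of the libraries did not give as many genes. Of 100 splits of the 14 libraries into 7 and 7, 1 gave as many genes higher and 1 as many genes lower, in each case the real split with 325 and 271, and the highest count in any other split was 4.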
